A study of Mus musculus with 6 samples.

How the data were processed

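RNA was sequenced from GFP-positive CD45-negative cells sorted from mouse lung tumours, 3 libraries per genotype. Per the labels' protocols, lungs were digested with collagenase and DNase, red cells were lysed, and libraries were made with the Nextera XT kit. The authors deposited expected counts per gene, and the submitters' processing notes name FastQC, STAR, RSEM and DESeq2 with genome build GRCm38, without versions. The strand setting and the annotation release are not given in the sources used here. RSEM divides reads that match several genes between them, so levels of genes with near-identical copies are uncertain, and without a known strand setting reads of overlapping antisense genes cannot be told apart. Of the genes named here, Stk11, Stat3, Psmb9, Tap2, Fn1, Sox17 and others have exons that overlap those of another gene. The table held 55487 genes.

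The expected counts were rounded to whole numbers. Genes were kept with filterByExpr, which left 15978, and libraries were scaled with TMM in edgeR 4.0.16 (R 4.3.3). CPM values are relative to these scaled library sizes. The genotypes were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided), with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a gene comes from this test unless another tool is named. The log2 fold change is sgLkb1 minus sgNeo, and its SE is the absolute log2 fold change divided by the square root of the F statistic. A fold against a group with no counts was computed against 3 counts over the group. Log2 fold changes printed for fits that left out a library are edgeR's own, without this floor. Floors cover counting error only, since the reads carried no molecular identifiers used here. A count of 3 corresponds to 0.12 CPM in each sgNeo library and to 0.073 to 0.086 CPM in sgLkb1 libraries.

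There were 47 gene lists, all tested, written before the data were examined, as were the tests and the other settings tried, apart from those named below. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. With that correlation 16 lists were higher and 8 lower. When the correlation was estimated for each list 0 were called, and 24 lists had lost their calls. An estimate from 6 libraries leaves this test little power, so the lost calls alone do not decide against a list. The alveolar type 2 list, with 24 of 25 members lower, then had a camera adjusted p of 0.38. The LKB1-SIK-CRTC list, with 7 of 22 higher, had the same value. Members were counted from the edgeR test, adjusted over all genes and over the list alone.

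Genes were named by a rule fixed beforehand. It takes a set that includes Stk11, Trp53, Lif, Lifr and Il6st, the 12 genes with the greatest rise and the 12 with the greatest fall past the threshold, and from each list the first 2 members and the 4 with the lowest p. The 12 genes needed a mean of at least 5 CPM in the higher group and no overlap of the groups, and gene models without a descriptive name, pseudogenes and immunoglobulin or T-cell receptor segments were passed over. The rule gives 271 genes, of which 2 are not reported here and the other 269 entered the alternatives. The text prints part of them, and that part was chosen with their values in view.

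Alternatives were RLE and upper-quartile scaling, no filter on low counts, a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, a robust dispersion, the replicate number as a block, and each library left out in turn. For lists they were an estimated correlation, fry, the block, RLE scaling, the stricter filter and each library left out. Removal of the 10 most abundant genes and the counts of list members and the limits of folds with a library left out were added after seeing the data. The rule for weighing stromal RNA as a source of the fibroblast calls was changed after its first result, to compare all left-out libraries. The first rule looked only at the fit without sgLkb1 replicate 3, and its result went with stromal RNA there as the source. The changed rule could not give that result, because 0 of the called genes passed without sgNeo replicate 2 or 3. The rule for the STAT3-induced list was also changed after its result, so that an overlap decides nothing where members go both ways. The written rule for the mesenchymal list was reworded after its result to state the sgNeo level its calculation had used. On simulated data with the real means and library sizes, run on 15978 genes, 50 genes were changed at each fold. The test recovered 2% of those changed 1.5-fold, 20% changed 2-fold, 92% changed 4-fold and 98% changed 8-fold. It called 4 of 15753 unchanged genes. The changed genes had a mean of at least 5 CPM and were far fewer than the genes that passed in the real data. The adjusted threshold was therefore stricter in the simulation, and recovery in the real data may be higher. Replicates were checked before averaging: Pearson correlations of log2 CPM were 0.95 to 0.96 within groups and 0.88 to 0.91 between groups, and no pair agreed within sampling noise (chi-square per degree of freedom at least 38.2). A test of scaling to surfactant transcripts as a source of the MHC class II falls was dropped, because the other scalings moved the median log2 fold change of all genes by little (0.018 to 0.048 at most). Coordinates are from GENCODE M21 on GRCm38.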

Results

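The data were bulk RNA sequencing libraries from tumour cells of the KP mouse model of lung adenocarcinoma. Tumours received either sgNeo, a control guide that leaves Lkb1 wild type, or sgLkb1, a guide against Lkb1 (gene symbol Stk11), the kinase that activates AMPK and the SIK kinases. GFP-positive CD45-negative cells were sorted from digested lungs 11 weeks after tumour initiation, which takes the tumour cells and leaves out most leukocytes. There were 3 libraries per genotype. Total counts were 28986526, 26007503 and 26448704 in sgNeo replicates 1, 2 and 3, and 41729299, 34286206 and 29613678 in sgLkb1 replicates 1, 2 and 3. The labels call these samples replicates and do not state that they came from separate animals, so the p-values measure the spread between these samples, which may be technical. The comparison asks which transcripts differ between Lkb1-mutant and Lkb1-wild-type tumour cells.

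Stk11, the targeted gene, was lower in sgLkb1 libraries. Its level was 68.3, 33.4 and 82.7 CPM in sgNeo replicates 1, 2 and 3, and 23.5, 25.6 and 25.3 CPM in sgLkb1 replicates 1, 2 and 3. The group means were 61.5 ± 25.4 and 24.8 ± 1.14 CPM (SD, n = 3), a log2 fold change of -1.31 (SE 0.30, edgeR adjusted p = 0.023). All sgLkb1 libraries lay below all sgNeo libraries, and transcript remained in every sgLkb1 library. The call was lost in 5 of 6 fits that left out a library, with edgeR adjusted p up to 0.076 and log2 fold changes from -1.61 to -1.04. Stk11 lies on chromosome 10 from 80115803 to 80130682 on the plus strand (GRCm38), and an exon of it overlaps one of Cbarp on the other strand. Trp53 was at 5.53 ± 0.52 and 7.53 ± 3.50 CPM and did not pass the test (edgeR adjusted p = 0.45).

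**Figure D1:**
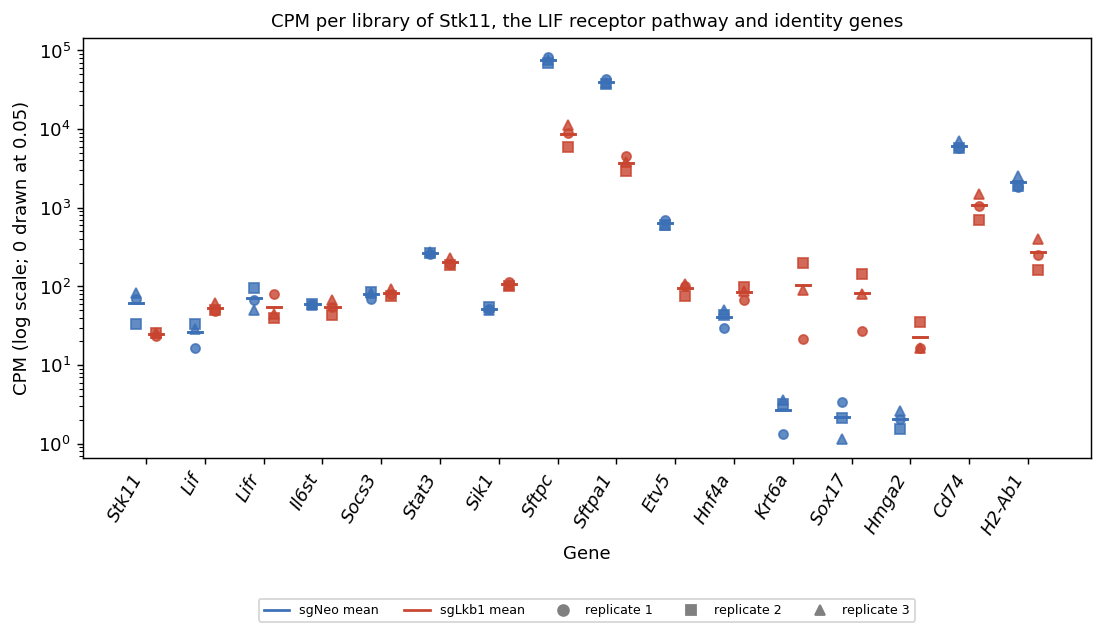
CPM of 16 genes in each library on a log axis, with sgNeo in blue, sgLkb1 in red, a symbol for each replicate and a line at each group mean. Sftpc falls from a mean of 75931 to 8691 CPM, whereas Lifr, Il6st, Socs3 and Stat3 did not pass the test.

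Between the genotypes 2501 of 15978 tested genes passed the threshold, with 1127 higher and 1374 lower in sgLkb1. Of these, 871 higher and 940 lower genes had a fold of 2 or more. The highest-ranked genes in sgLkb1 by fold included Slc17a6, a vesicular glutamate transporter, at 0.066 ± 0.083 CPM in sgNeo and 43.4 ± 25.2 CPM in sgLkb1 (log2 fold change 9.26, SE 0.76). Cxcl13, a chemokine for B cells, rose from 0.067 ± 0.023 to 26.4 ± 22.97 CPM, and Acan, a cartilage proteoglycan, from 0.040 ± 0.040 to 13.6 ± 8.47 CPM. Ror2, a receptor for Wnt5a, rose from 0.067 ± 0.12 to 13.9 ± 2.52 CPM, and Ifitm1 from 1.55 ± 0.58 to 227 ± 232 CPM. Spock3, Nat8l, Pate14 and Ush1g had no counts in any sgNeo library and were at least 247-fold, 159-fold, 157-fold and 148-fold higher, against a floor of 3 counts over the group. Without sgLkb1 replicate 2 these limits were 125-fold, 101-fold, 105-fold and 92.96-fold, and with a sgNeo library left out they lay between 97.9-fold and 165-fold. With a library left out, the log2 fold change was 10.82 for Slc17a6 without sgNeo replicate 3 and 7.60 for Cxcl13 without sgLkb1 replicate 3. It was 9.15 for Acan without sgNeo replicate 2, 11.82 for Ror2 without sgNeo replicate 1 and 6.03 for Ifitm1 without sgLkb1 replicate 2. The remaining sgNeo libraries held no counts of Ror2, so 11.82 is edgeR's value without a floor and not a measured fold. Tmprss6, Syt13 and Ramp3 were also among the 12 genes with the greatest rise (log2 fold changes 9.35, 8.65 and 7.77). Their sgNeo levels were 0.013 ± 0.023, 0.013 ± 0.023 and 0.17 ± 0.27 CPM. For Tmprss6 and Syt13, as for Slc17a6, Cxcl13, Acan and Ror2, the sgNeo mean was below the 0.12 CPM of 3 counts in a sgNeo library. The size of these folds is therefore uncertain. Without sgNeo replicate 1 the values were 11.53 for Tmprss6 and 10.66 for Ramp3, without sgLkb1 replicate 2 they were 8.33 and 6.91, and without sgNeo replicate 2 it was 10.83 for Syt13. The values 11.53 for Tmprss6 and 10.83 for Syt13 are also not measured folds, since the remaining sgNeo libraries held no counts of the gene. Among the 12 genes with the greatest fall, Chia1, an acidic chitinase, went from 2337 ± 222 to 47.3 ± 15.4 CPM (log2 fold change -5.63, SE 0.32, edgeR adjusted p = 0.00017) and Acoxl from 255 ± 24.9 to 7.21 ± 3.00 CPM. Bex4 fell from 51.0 ± 5.58 to 0.36 ± 0.25 CPM and the complement component C6 from 101 ± 18.9 to 3.43 ± 2.05 CPM. Cyp2c68 had no counts in sgLkb1 and was at least 281-fold lower (179-fold without sgLkb1 replicate 1 and 183-fold without sgLkb1 replicate 2), and reads of it can be shared with close Cyp2c copies. Npy2r, Habp2, Spink5, Pygo1, Ly6i, Tmem132d and Myh13 were the others, with log2 fold changes from -7.78 to -4.86. Ly6i belongs to a family of near-identical genes, so its level is uncertain, and Tmem132d lost its call in 4 of 6 fits that left out a library (edgeR adjusted p up to 0.091). Without sgLkb1 replicate 3 the log2 fold change was -10.68 for Tmem132d against -4.93 in all libraries, -7.00 for Pygo1 against -5.32 and -7.39 for Habp2 against -6.43 (-5.78 without sgNeo replicate 2). Ly6i was at -4.14 without sgNeo replicate 3 against -5.01, and Tmem132d at -4.29 without sgLkb1 replicate 1 and -4.30 without sgLkb1 replicate 2. Without sgLkb1 replicate 2 the log2 fold change was -11.01 for Npy2r against -7.78. The values -10.68 for Tmem132d and -11.01 for Npy2r are not measured folds, since the remaining sgLkb1 libraries held no counts of the gene. The total count was 1129 without sgNeo replicate 2, 1325 without sgNeo replicate 1, 1587 without sgNeo replicate 3 and 1529 without sgLkb1 replicate 2.

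Alveolar type 2 identity genes, which make surfactant, were lower in sgLkb1 tumour cells. Of 25 measured members 24 fell and none rose, with a median log2 fold change of -2.34. Sftpc, surfactant protein C, fell from 75931 ± 6733 to 8691 ± 2660 CPM (log2 fold change -3.13, SE 0.31, edgeR adjusted p = 0.00088). Sftpa1 fell from 39865 ± 2970 to 3722 ± 811 CPM, and Sftpb from 5824 ± 792 to 2220 ± 436 CPM. Etv5, a transcription factor that maintains type 2 cells, fell from 637 ± 57.3 to 94.7 ± 16.7 CPM, and Lpcat1, which makes surfactant lipid, from 1323 ± 56.0 to 179 ± 45.5 CPM. Sftpc, Sftpa1 and Lyz2 together took 12.6 to 14.1% of all counts in sgNeo libraries and 1.19 to 2.07% in sgLkb1 libraries, a sum chosen after the values were seen. Adjusted over the list alone, 25 members fell. Camera gave an adjusted p of 2.9e-18 with the preset correlation, and the adjusted p = 0.38 with an estimated correlation. The list of fatty acid synthesis and surfactant lipid had 12 of 21 members lower, 7 without sgNeo replicate 1 or 2, 15 lower and 1 higher when adjusted over the list alone (camera adjusted p = 8.9e-06; adjusted p = 0.38 with an estimated correlation). Fasn, the fatty acid synthase, fell from 862 ± 55.3 to 319 ± 66.1 CPM, Acaca from 50.8 ± 3.05 to 16.1 ± 1.99 CPM and the surfactant lipid transporter Abca3 from 660 ± 22.97 to 133 ± 39.0 CPM.

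In the gastric and hindgut list 8 of 24 members rose (4 without sgNeo replicate 2) and 1 fell, and 10 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0010; adjusted p = 0.62 with an estimated correlation). Tff1, a gastric trefoil peptide, rose from 78.1 ± 71.8 to 957 ± 399 CPM (log2 fold change 3.62, SE 0.69), Anxa10 from 13.1 ± 12.4 to 234 ± 66.2 CPM and Pdx1 from 0.13 ± 0.16 to 3.54 ± 0.89 CPM. Without sgNeo replicate 3 their log2 fold changes were 4.67, 5.28 and 6.32, against 3.62, 4.16 and 4.69 in all libraries. Hnf4a, a master regulator of gut epithelium, rose from 40.7 ± 10.3 to 83.9 ± 15.3 CPM (edgeR adjusted p = 0.019), and lost its call in 3 of 6 fits that left out a library, with adjusted p up to 0.075. Gkn2 was at 147 ± 95.3 and 237 ± 108 CPM and did not pass. In the basal and squamous list 9 of 17 members rose (5 without sgNeo replicate 1 and 4 without sgNeo replicate 2), 10 when adjusted over the list alone (camera adjusted p = 1.8e-05; adjusted p = 0.38 with an estimated correlation). Krt6a, a squamous keratin, rose from 2.70 ± 1.21 to 105 ± 90.4 CPM (log2 fold change 5.27, SE 0.81, and 4.43 without sgLkb1 replicate 2), and Pkp1 from 1.00 ± 0.36 to 32.1 ± 19.3 CPM. Trp63 and Krt5, regulators and markers of basal cells, were at most 4.52 CPM on average and did not pass. The Krt8-high transitional alveolar list had 7 of 23 members higher (2 without sgNeo replicate 1 or 2), 9 when adjusted over the list alone (camera adjusted p = 0.0043; adjusted p = 0.57 with an estimated correlation). Krt19 rose from 676 ± 98.1 to 1709 ± 445 CPM and Plaur from 140 ± 36.1 to 290 ± 23.8 CPM; each lost its call without sgNeo replicate 2 (edgeR adjusted p = 0.051 and 0.066), Plaur also without sgNeo replicate 1 (edgeR adjusted p = 0.063).

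In the list of embryonic and metastatic lung tumour genes 5 of 13 members rose (8 without sgLkb1 replicate 1), 10 when adjusted over the list alone (camera adjusted p = 2.2e-05; adjusted p = 0.38 with an estimated correlation). Sox17, an endoderm transcription factor, rose from 2.22 ± 1.13 to 83.8 ± 58.3 CPM (log2 fold change 5.23, SE 0.67, edgeR adjusted p = 0.0023, and 4.64 without sgLkb1 replicate 2). Hmga2, a chromatin protein of embryonic tissue, rose from 2.06 ± 0.53 to 22.7 ± 10.8 CPM, Sox9 from 25.4 ± 5.47 to 79.7 ± 17.1 CPM and Runx2 from 4.06 ± 0.98 to 15.2 ± 3.45 CPM. Mesenchymal transition genes rose in 10 of 20 members, 14 when adjusted over the list alone (camera adjusted p = 3.1e-06; adjusted p = 0.38 with an estimated correlation). Itgb3, an integrin subunit, rose from 3.58 ± 0.93 to 74.8 ± 21.6 CPM (log2 fold change 4.38, SE 0.29). Vim rose from 28.7 ± 7.34 to 84.8 ± 31.04 CPM, Fn1 from 139 ± 30.2 to 938 ± 611 CPM and Lox from 1.17 ± 0.77 to 17.1 ± 16.2 CPM, and all 3 lost their calls without sgNeo replicate 2 (edgeR adjusted p = 0.063, 0.054 and 0.063 at most), Vim also without sgNeo replicate 1. Zeb1 was at 1.69 ± 0.38 and 4.24 ± 1.88 CPM and did not pass (edgeR adjusted p = 0.094). Markers of 3 other cell types were higher beside this list: 4 of 19 fibroblast, 4 of 9 mesothelial and 5 of 20 endothelial markers rose (adjusted p = 0.66, 0.44 and 0.66 with an estimated correlation). Col3a1 was at 24.4 ± 13.3 and 265 ± 311 CPM, highest in sgLkb1 replicate 3, and lost its call when any sgNeo library was left out (edgeR adjusted p up to 0.12). Aldh1a2, of the mesothelial list, was at 13.5, 138 and 57.0 CPM in sgLkb1 replicates 1, 2 and 3 (log2 fold change 5.67, 6.70 without sgNeo replicate 1 and 4.74 without sgLkb1 replicate 2). Without sgNeo replicate 2, 1 mesenchymal member passed, and 5 without sgNeo replicate 1 or 3. Without sgLkb1 replicate 3, 5 of 20 mesenchymal members and 1 of 19 fibroblast members passed. There the log2 fold change was 1.80 for Col3a1 against 3.44 in all libraries and 2.73 for Lox against 3.87. Epithelial junction genes had 3 of 21 higher and 1 lower and were not called. Without sgNeo replicate 1 or 2 none passed, and without sgNeo replicate 3 or sgLkb1 replicate 2 there was 1 higher. Cdh1 was at 949 ± 59.4 and 1048 ± 63.8 CPM, with Epcam higher (501 ± 60.2 to 1073 ± 235 CPM), a call lost without sgNeo replicate 1 or 2 (edgeR adjusted p up to 0.059). Matrix remodelling enzymes had 9 of 28 higher and 4 lower, 15 and 6 when adjusted over the list alone (camera adjusted p = 0.0040; adjusted p = 0.62 with an estimated correlation). They had 4 higher and 1 lower without sgNeo replicate 2, and 2 lower without sgNeo replicate 1 or 3. Mmp7, a matrix metalloproteinase, rose from 0.36 ± 0.38 to 43.0 ± 40.3 CPM (log2 fold change 6.88, 8.21 without sgNeo replicate 3 and 5.85 without sgLkb1 replicate 2) and Mmp14 from 85.7 ± 10.6 to 345 ± 90.6 CPM, while Adamts1 fell from 218 ± 19.4 to 52.8 ± 15.5 CPM.

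**Figure D2:**
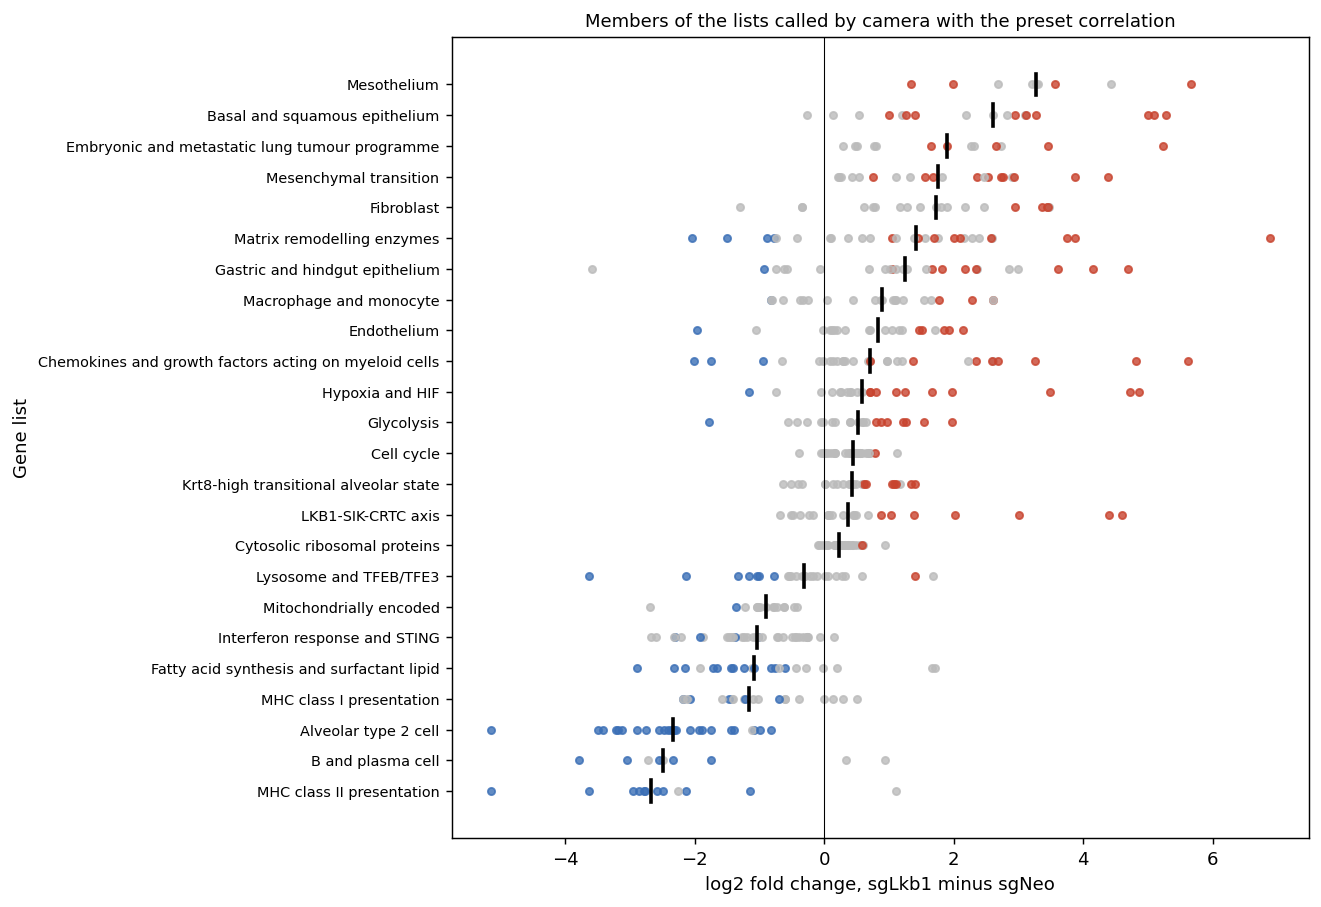
log2 fold change, sgLkb1 minus sgNeo, of each member of the 24 lists called by camera with the preset correlation, with a black bar at the list median. Red and blue members passed the edgeR threshold and grey ones did not. The alveolar type 2 members lie to the left of 0, with a median of -2.34.

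Of 12 MHC class II members 10 fell, and 10 fell and 1 rose when adjusted over the list alone (camera adjusted p = 4.6e-07; adjusted p = 0.38 with an estimated correlation). Cd74, the invariant chain, fell from 6171 ± 778 to 1094 ± 404 CPM (log2 fold change -2.50, SE 0.30, edgeR adjusted p = 0.0018). H2-Aa fell from 1278 ± 176 to 175 ± 63.2 CPM, H2-Ab1 from 2095 ± 390 to 271 ± 122 CPM and H2-Eb1 from 481 ± 87.6 to 70.1 ± 22.2 CPM. Of 9 B and plasma cell markers 5 were also lower, 2 without sgLkb1 replicate 3. In the MHC class I list 5 of 20 members fell, 13 when adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.66 with an estimated correlation). The number that fell was 9 without sgLkb1 replicate 3, 8 without sgNeo replicate 1, 1 without sgLkb1 replicate 1 and 0 without sgNeo replicate 2, sgNeo replicate 3 or sgLkb1 replicate 2. Tap2, a peptide transporter, fell from 99.2 ± 29.8 to 35.9 ± 14.4 CPM and Psmb9 from 47.5 ± 26.2 to 11.2 ± 6.90 CPM, and each lost its call in 4 of 6 fits that left out a library (edgeR adjusted p up to 0.069 and 0.096). H2-K1 was at 2041 ± 913 and 758 ± 341 CPM and B2m at 957 ± 448 and 404 ± 174 CPM, and neither passed (edgeR adjusted p = 0.051 and 0.087). Of 34 interferon response and STING genes 4 fell, 2 when adjusted over the list alone (camera adjusted p = 0.00078; adjusted p = 0.66 with an estimated correlation). The number that fell was 11 without sgNeo replicate 1, 0 without sgNeo replicate 2 or 3 and 1 without sgLkb1 replicate 2. Ifit2 fell from 10.5 ± 5.77 to 2.13 ± 0.69 CPM and Bst2 from 50.3 ± 25.9 to 19.4 ± 6.73 CPM, with edgeR adjusted p up to 0.069 and 0.15 over the fits that left out a library. Sting1 was at 48.8 ± 9.61 and 38.7 ± 8.78 CPM and Cgas below 1 CPM, and neither passed. T-cell regulating ligands and ectoenzymes had 4 of 20 higher (2 without sgNeo replicate 2) and 3 lower and were not called. Vtcn1, an inhibitory ligand, rose from 0.39 ± 0.29 to 7.11 ± 4.05 CPM (log2 fold change 4.18, and 4.86 without sgNeo replicate 2), Entpd1 fell from 160 ± 14.9 to 44.1 ± 13.8 CPM, and Cd274 was at 6.71 ± 4.69 and 2.74 ± 1.82 CPM without passing.

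Secreted factors acting on myeloid cells changed in both directions, with 8 of 29 higher (3 without sgNeo replicate 1 or 2) and 3 lower, 11 and 4 when adjusted over the list alone (camera adjusted p = 0.0068; adjusted p = 0.38 with an estimated correlation). Il1a rose from 6.30 ± 0.20 to 60.3 ± 13.8 CPM (log2 fold change 3.26, SE 0.21, edgeR adjusted p = 0.00024), and Csf2 fell from 19.5 ± 1.73 to 5.80 ± 1.89 CPM. Cxcl1 was at 24.6 ± 6.64 and 48.2 ± 16.8 CPM and Cxcl2 at 8.40 ± 1.97 and 8.29 ± 0.83 CPM, and neither passed. Lif, a cytokine of the IL-6 family, rose from 26.4 ± 9.03 to 53.6 ± 6.85 CPM (log2 fold change 1.02, SE 0.26, edgeR adjusted p = 0.035). The call was lost in 5 of 6 fits that left out a library, with edgeR adjusted p up to 0.088. Its receptor Lifr was at 71.0 ± 23.1 and 54.6 ± 21.8 CPM, and the shared receptor Il6st at 59.7 ± 0.94 and 55.4 ± 12.4 CPM, and neither passed (edgeR adjusted p = 0.47 and 0.74). Il6 rose from 1.45 ± 0.86 to 9.99 ± 5.63 CPM and lost its call without sgNeo replicate 2 (edgeR adjusted p = 0.073). The IL-6 family list had 2 of 13 higher and 1 lower, and was not called (camera adjusted p = 0.64). It had 0 higher without sgNeo replicate 2 and 1 without sgNeo replicate 1, sgNeo replicate 3, sgLkb1 replicate 2 or sgLkb1 replicate 3. STAT3-induced genes had 2 of 23 higher and 3 lower, 2 and 5 when adjusted over the list alone, and were not called (camera adjusted p = 0.58). The counts were 1 higher and 1 lower when any sgNeo library was left out. The median of this list was 0.06 and its mean 0.24, while camera pointed down. Socs3, a STAT3 target, was at 79.8 ± 8.49 and 82.9 ± 7.89 CPM and Stat3 at 267 ± 6.56 and 204 ± 22.1 CPM, and neither passed (edgeR adjusted p = 0.84 and 0.12). Lcn2 fell from 1252 ± 190 to 279 ± 50.3 CPM and Timp1 rose from 4.59 ± 2.41 to 61.7 ± 40.8 CPM (log2 fold change 3.75, and 3.15 without sgLkb1 replicate 3).

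The list for the LKB1-SIK-CRTC axis had 7 of 22 members higher, 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0095; adjusted p = 0.38 with an estimated correlation). Sik1 rose from 51.9 ± 2.17 to 107 ± 5.61 CPM (log2 fold change 1.04, SE 0.13, edgeR adjusted p = 0.0023). Nr4a2, a nuclear receptor induced by CREB, rose from 16.7 ± 2.62 to 67.9 ± 4.73 CPM, and Pde4b, a cAMP phosphodiesterase, from 13.1 ± 3.71 to 105 ± 28.6 CPM. Nr4a1 was at 114 ± 12.4 and 102 ± 6.13 CPM and did not pass. The list of LKB1 complex and AMPK subunits had 3 of 18 lower and was not called (camera adjusted p = 0.41; 1 lower without sgNeo replicate 3 or sgLkb1 replicate 2), and Prkaa2, an AMPK catalytic subunit, fell from 9.13 ± 3.59 to 2.27 ± 0.16 CPM. Hypoxia genes had 10 of 21 higher and 1 lower, 11 and 2 when adjusted over the list alone (camera adjusted p = 0.00039; adjusted p = 0.38 with an estimated correlation). Those higher numbered 5 without sgNeo replicate 1, 4 without sgNeo replicate 2, and 6 without sgNeo replicate 3 or sgLkb1 replicate 2. Car9, a carbonic anhydrase, rose from 5.69 ± 4.80 to 63.7 ± 24.6 CPM (log2 fold change 3.48, and 4.43 without sgNeo replicate 3) and Adm from 0.62 ± 0.37 to 16.4 ± 4.84 CPM. Glycolysis genes had 7 of 21 higher (3, 2 and 4 without sgNeo replicate 1, sgNeo replicate 2 and sgLkb1 replicate 2) and 1 lower, 10 and 1 when adjusted over the list alone (camera adjusted p = 0.00998; adjusted p = 0.62 with an estimated correlation), with Pgk1 rising from 124 ± 22.3 to 361 ± 39.9 CPM and Pfkfb4 falling from 82.9 ± 3.66 to 24.03 ± 5.79 CPM. Lysosome and TFEB/TFE3 genes had 7 of 25 lower (4 without sgNeo replicate 1 or sgLkb1 replicate 2) and 1 higher, 9 and 2 when adjusted over the list alone (camera adjusted p = 0.020; adjusted p = 0.38 with an estimated correlation). Mitf fell from 14.7 ± 2.40 to 1.18 ± 0.30 CPM and Flcn from 99.0 ± 9.42 to 39.4 ± 3.50 CPM, while Ctsl rose from 164 ± 9.25 to 435 ± 78.9 CPM. Cell cycle genes had 1 of 28 higher, Birc5, and none when adjusted over the list alone (camera adjusted p = 0.0081, and adjusted p = 0.66 with an estimated correlation). Mki67 was at 13.9 ± 3.20 and 22.1 ± 6.57 CPM without passing. Without sgLkb1 replicate 2 the camera calls of the cell cycle and lysosome lists were lost (camera adjusted p = 0.11 and 0.053).

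Markers of other cells were counted because the sort could still hold them. Fibroblast markers had 4 of 19 higher (0 without sgNeo replicate 2 or 3, and 1 without sgLkb1 replicate 3), 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0081; adjusted p = 0.66 with an estimated correlation). Col1a1 rose from 15.3 ± 10.4 to 118 ± 113 CPM (log2 fold change 2.95, 1.81 without sgLkb1 replicate 3 and 3.65 without sgNeo replicate 1), with edgeR adjusted p up to 0.13 over the fits that left out a library. Mesothelial markers had 4 of 9 higher, 9 when adjusted over the list alone (camera adjusted p = 0.00072; adjusted p = 0.44 with an estimated correlation), and Msln rose from 261 ± 143 to 1033 ± 232 CPM (edgeR adjusted p = 0.056 without sgNeo replicate 2). Mesothelial members higher numbered 1 without sgNeo replicate 2, and 10 without sgLkb1 replicate 1, where more members were tested. Endothelial markers had 5 of 20 higher and 1 lower, 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0088; adjusted p = 0.66 with an estimated correlation; camera adjusted p = 0.11 without sgLkb1 replicate 3), with Flt1 rising from 13.2 ± 3.29 to 47.5 ± 8.47 CPM. Their number higher was 2 without sgNeo replicate 1, and 3 without sgNeo replicate 2, sgNeo replicate 3 or sgLkb1 replicate 3. Macrophage and monocyte markers had 3 of 22 higher (1 without sgNeo replicate 2 and 6 without sgLkb1 replicate 2) and 1 lower, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.042; adjusted p = 0.66 with an estimated correlation), and that camera call was lost under 3 of the fits that left out a library. B and plasma cell markers had 5 of 9 lower, 6 when adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.38 with an estimated correlation), with Fcer2a falling from 42.7 ± 1.16 to 5.13 ± 2.18 CPM. The number lower was 2 without sgLkb1 replicate 3 and ran from 1 to 4 over the fits that left out a library. Pan-leukocyte markers had 1 of 15 higher and 2 lower, neutrophil markers 1 of 10 higher, T and NK cell markers 1 of 5 higher, platelet markers 2 of 6 higher and 1 lower, and erythroid markers 0 of 6 changed, and none of these lists was called. Ptprc, which encodes CD45, was at 7.23 ± 2.10 and 6.70 ± 3.24 CPM and did not pass (edgeR adjusted p = 0.89). Mitochondrially encoded genes had 1 of 15 lower, mt-Nd2, and none when adjusted over the list alone (camera adjusted p = 0.0095; adjusted p = 0.71 with an estimated correlation). Mitochondrial counts were 3.00 to 8.25% of the total in sgNeo and 2.75 to 5.20% in sgLkb1 libraries. Cytosolic ribosomal protein genes had 1 of 30 higher, Rps16, and none when adjusted over the list alone (camera adjusted p = 0.0058; adjusted p = 0.66 with an estimated correlation). Birc5, mt-Nd2 and Rps16 each lost the call in at least 4 fits that left out a library, with edgeR adjusted p up to 0.11, 0.12 and 0.14.

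**Figure D3:**
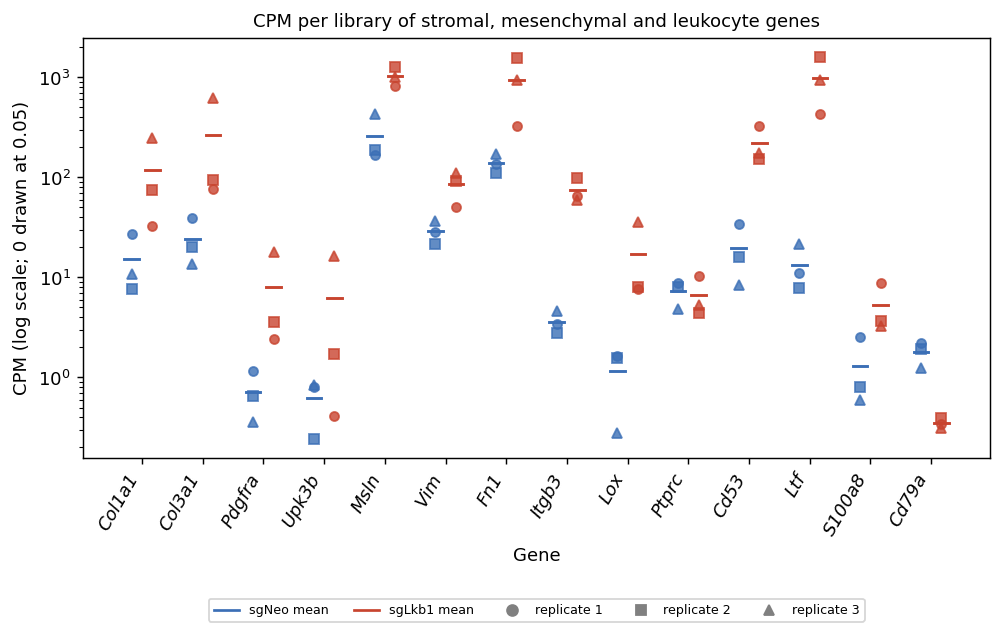
CPM of 14 stromal, mesenchymal and leukocyte genes in each library on a log axis, with sgNeo in blue, sgLkb1 in red, a symbol for each replicate and a line at each group mean. Col3a1 has a mean of 24.4 CPM in sgNeo and 265 CPM in sgLkb1, and sgLkb1 replicate 3 lies highest.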

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

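Removal of the 10 most abundant genes and the counts of list members and limits of folds with a library left out were chosen after seeing the data, and the other settings were set beforehand. Of the 2501 genes, 2425 also passed under RLE scaling, 2430 under upper-quartile scaling, 2441 in DESeq2, 2166 in limma-voom and 2447 with the 10 most abundant genes removed. Genes higher and lower in sgLkb1 numbered 1127 and 1374 in edgeR, 1917 and 1523 with no filter on low counts, where more genes were tested, 1786 and 1626 in DESeq2 and 878 and 1401 in limma-voom. More genes were higher than lower only with no filter and in DESeq2, which both tested more genes (31803 and 18819 against 15978), and whether the genes tested or the tool turned the balance in DESeq2 was not tested. With a library left out, which leaves fewer samples, the count ran from 1129 to 2780 genes, with 447 to 1368 higher and 682 to 1412 lower, and the log2 fold change of Stk11 from -1.61 to -1.04. Of 172 called genes that the naming rule gives, 107 passed in every fit that left out a library and 151 under RLE, upper-quartile, DESeq2 and limma-voom alike. The fold of 42 of these genes moved by over 1.5 times in some fit that left out a library: Psmb9 to -2.71 without sgLkb1 replicate 3, Calca to 3.95 without it, Pf4 to -2.86 without sgNeo replicate 1, Cd53 to 4.14 without it and Ppbp to 2.54 without sgLkb1 replicate 2 are examples on the log2 scale. Deviations of same-numbered libraries correlated weakly, at 0.13, -0.02 and 0.11. Mitochondrial counts fell with the replicate number in both groups (8.25, 5.78 and 3.00% in sgNeo, 5.20, 3.93 and 2.75% in sgLkb1). Whether the replicate numbers pair the libraries thus stays open. The replicate block gave 2880 genes, of which 2308 were among the 2501. It turned Cgas to 0.042, Csf1r to -0.0042, and the directions of the neuroendocrine (adjusted p = 0.79), T and NK cell (0.98) and platelet lists (0.74). Genes that had not passed also turned direction in log2 fold change elsewhere: in limma-voom Cgas 0.24, Csf1r -0.021 and Cxcl2 0.0029, under RLE Cxcl2 0.0084 and Nfkbia 0.019, with no filter Cxcl2 0.015 and Nfkbia 0.026, in DESeq2 Cxcl2 0.0093 and Nfkbia 0.019, and under upper-quartile scaling Nfkbia 0.0069. With a library left out the ranges that crossed 0 were Trp53 -0.0061 to 0.71, Il6st -0.29 to 0.078, Atf4 -0.044 to 0.25, Cd247 -0.11 to 1.04, Cdkn1a -0.066 to 0.081, Cgas -0.79 to 0.66, Cldn4 -0.17 to 0.19, Csf1r -0.26 to 0.36, Cxcl2 -0.13 to 0.18, Gclc -0.13 to 0.47 and Hbb-bs -0.81 to 0.19. The same held for Hmgcs1 -0.27 to 0.0083, Krt5 -0.79 to 3.88, Ndufa2 -0.20 to 0.00014, Nfkb1 -0.031 to 0.23, Nfkbia -0.10 to 0.11, Ptprc -0.56 to 0.15, Scgb1a1 -1.38 to 0.31, Socs3 -0.037 to 0.14, Strada -0.26 to 0.020 and Trp63 -0.33 to 2.07. With an estimated correlation, a setting with little power at 6 libraries, all 24 list calls were lost. The adjusted p was 0.38 for the SIK-CRTC, type 2, basal, embryonic, mesenchymal, myeloid chemokine, MHC class II, hypoxia, fatty acid, lysosome and B cell lists, and 0.44 for mesothelium. It was 0.57 for the Krt8-high list, 0.62 for gastric, matrix and glycolysis, 0.71 for mitochondrial genes, and 0.66 for MHC class I, interferon, cell cycle, macrophage, fibroblast, endothelium and ribosomal proteins. With fry, which does not compare a list with other genes, the adjusted p was 0.085 for gastric and ribosomal proteins, 0.058 for matrix, 0.13 for MHC class I, 0.22 for interferon and fibroblast, 0.27 for cell cycle and mitochondrial genes, 0.073 for glycolysis, 0.15 for macrophage and 0.21 for endothelium. It passed for AMPK subunits (0.028), p53-induced genes (0.014) and neutrophils (0.019), and the directions of cholesterol and nitrogen genes turned (both 0.83). The macrophage list also lost its call under RLE (0.056) and the stricter filter (0.10); the cause was not tested. With a library left out, camera adjusted p ran from 0.028 to 0.31 for type 1 cells, 0.018 to 0.99 for ciliated cells, 0.68 to 0.93 for junctions, 0.51 to 0.89 for NF-kB, 0.55 to 0.998 for T-cell ligands, 0.00085 to 0.11 for cell cycle, 0.64 to 0.99 for cholesterol and 0.013 to 0.053 for lysosome. It ran from 0.26 to 0.92 for pan-leukocyte, 0.0037 to 0.20 for macrophage, 0.034 to 0.21 for neutrophil, 0.58 to 0.92 for T and NK cell, 0.0033 to 0.11 for endothelium, 0.58 to 0.998 for platelet, 3.0e-05 to 0.11 for mitochondrial and 0.0017 to 0.059 for ribosomal genes. Camera's direction turned in some of these fits for the ciliated, junction, NF-kB, T-cell ligand, cholesterol and pan-leukocyte lists. For the T and NK cell and platelet lists it turned in every such fit except the one without sgNeo replicate 1. List members past the threshold also moved with a library left out. Those higher ran from 2 to 9 for Krt8-high, 4 to 11 for gastric, 4 to 8 for basal, 4 to 8 for embryonic, 1 to 12 for mesenchymal, 4 to 13 for matrix and 3 to 11 for myeloid chemokine genes. They ran from 2 to 8 for glycolysis, 4 to 10 for hypoxia, 1 to 6 for macrophage, 0 to 6 for fibroblast, 2 to 7 for endothelium and 1 to 10 for mesothelium. Those lower ran from 0 to 9 for MHC class I, 0 to 11 for interferon, 7 to 14 for fatty acid, 4 to 7 for lysosome and 1 to 4 for B cell genes, and for type 1 cells 3 to 8 were lower and 1 to 4 higher. For lists with no camera call, those higher ran from 0 to 4 for AP-1, 2 to 5 for NRF2, 1 to 5 for p53, 1 to 6 for nitrogen, 2 to 4 for T-cell ligand and 0 to 3 for junction genes, and those lower from 1 to 4 for AMPK subunits and 1 to 3 for STAT3-induced genes. Lists with 1 or 2 members past the threshold in a direction had 0 to 4 there. At 3 libraries per group the simulated recovery was 20% of 50 genes changed 2-fold. Far fewer genes were changed there than passed in the real data, so recovery in the real data may be higher. Genes that did not pass can still differ by 2-fold.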

Other observations

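Further lists with no camera call held single members that changed. Ciliated cell genes had 1 of 16 higher, Tmem212 (0.53 ± 0.12 to 6.21 ± 2.50 CPM). Club and secretory genes had 2 of 16 higher (0 without any sgNeo library or sgLkb1 replicate 2, and 1 without sgLkb1 replicate 1) and 2 lower (1 without sgNeo replicate 2, sgNeo replicate 3 or sgLkb1 replicate 3): Muc5b, an airway mucin, rose from 69.8 ± 39.3 to 283 ± 117 CPM, and Cbr2, a carbonyl reductase of club and type 2 cells, fell from 1252 ± 187 to 44.1 ± 16.7 CPM. Alveolar type 1 genes had 5 of 19 higher (1 without sgNeo replicate 2 or 3) and 5 lower (8 without sgLkb1 replicate 3), with Ager falling from 1967 ± 192 to 556 ± 165 CPM and Sema3e rising from 26.5 ± 5.64 to 67.9 ± 15.1 CPM. Neuroendocrine genes had 2 of 6 higher (0 without sgNeo replicate 2), among them Calca, the calcitonin gene (0.094 ± 0.047 to 4.12 ± 4.53 CPM); the median of this list was -0.57 and its mean 0.75. The calls of Muc5b, Calca and Ppbp were lost in 5, 1 and 2 of the 6 fits that left out a library, with edgeR adjusted p up to 0.088, 0.051 and 0.064. The platelet list also had a median of -0.60 against a mean of 0.33, with Pf4 lower (59.1 ± 38.0 to 5.18 ± 2.33 CPM) and Ppbp higher (4.93 ± 3.24 to 59.0 ± 54.2 CPM).

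NF-kB-induced genes had 2 of 20 higher and 2 lower, and AP-1 and immediate early genes 3 of 24 higher (0 without sgNeo replicate 1 or 2, and 1 without sgNeo replicate 3). NRF2-induced genes had 4 of 22 higher (2 without sgNeo replicate 1) and 3 lower, with Gstm1, a glutathione transferase, falling from 411 ± 77.8 to 101 ± 6.67 CPM and Gpx2 rising from 32.6 ± 6.44 to 111 ± 40.8 CPM. p53-induced genes had 3 of 21 higher and 2 lower (1 and 1 when any sgNeo library was left out, and 5 and 2 without sgLkb1 replicate 3), the integrated stress response 1 of 21 higher and 2 lower, and the unfolded protein response 3 of 19 lower. Nitrogen and nucleotide genes had 5 of 21 higher (1 without sgNeo replicate 1, 2 without sgNeo replicate 2, sgNeo replicate 3 or sgLkb1 replicate 2, and 3 without sgLkb1 replicate 3) and 3 lower, and Gpt, an alanine aminotransferase, fell from 87.7 ± 5.50 to 13.5 ± 1.34 CPM (edgeR adjusted p = 0.00017). Oxidative phosphorylation had 1 of 28 higher and cholesterol synthesis 1 of 23 lower.

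All tests in the paragraphs that follow, except those on splits of the libraries and on chromosomes, were chosen after the result was seen. The real split of the 6 libraries gave 2501 genes and the highest of the other 9 splits gave 0, with 1218 at an unadjusted p under 0.05 in that test of edgeR. Each of the other 9 splits put libraries of both genotypes on each side. The difference between genotypes then widened the spread within a side, so the 0 is no measure of what chance gives. Only 1 of 10 splits gave as many genes, and 10 splits are too few for a share under 0.05.

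Among fibroblast markers 4 of 19 rose, and among mesenchymal genes 10 of 20. RNA of stromal cells in sgLkb1 replicate 3 is a candidate source of the fibroblast calls, since all 4 genes were highest there. The test counted genes passing. It counted 1 of 4 without sgLkb1 replicate 3, against 4 of 4 without sgLkb1 replicate 1 or sgLkb1 replicate 2, fits with as many samples. It counted 2 without sgNeo replicate 1, and 0 without sgNeo replicate 2 or sgNeo replicate 3. Among sgLkb1 libraries the calls thus depended on replicate 3 alone. The test cannot tell, since its rule needed fewer genes without sgLkb1 replicate 3 than without any other library. The log2 fold changes of all 4 genes were smaller without sgLkb1 replicate 3. They went from 2.95 to 1.81 for Col1a1, 3.36 to 2.01 for Col1a2, 3.44 to 1.80 for Col3a1 and 3.45 to 2.03 for Pdgfra. That library thus carried part of the rise, and whether its part was stromal RNA was not tested. Of all measured members, whether called or not, 14 of 19 fibroblast, 14 of 20 endothelial and 10 of 20 mesenchymal genes were highest in sgLkb1 replicate 3. In sgLkb1 replicate 2 the numbers were 1, 1 and 7, and the rest were highest in other libraries. For the mesenchymal list, 9 of the 10 called members exceeded, in both other sgLkb1 libraries, the amount that would scale with the collagens of sgLkb1 replicate 3, a comparison that includes the expression also present in sgNeo. Above the highest sgNeo level plus that amount were 3 (Itgb3, Fn1 and Snai1, the last named after its values were seen), fewer than the 5 that would argue against stromal RNA as the whole source. That amount covers fibroblast RNA alone. Among mesothelial markers 4 of 9 rose: Msln, Krt19, Aldh1a2 and Cpe. All 4 were highest in sgLkb1 replicate 2, where Fn1 and Itgb3 were also highest. The other 5 markers were highest in sgLkb1 replicate 3 and did not pass over all genes. Krt19 is also a risen member of the Krt8-high list, so its rise need not mean mesothelial RNA. Both stromal RNA and a change in tumour cells that goes with the genotype stay open for the list.

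Of 12 MHC class II genes 10 were lower in sgLkb1. The fall in B and plasma cell genes was 0.58% of the fall in class II genes in summed CPM, which argues against fewer B cells, which the CD45 gate would remove, as the whole source. The limit for this share, 5%, was set with the value in view, and B cells may carry more class II transcript than these markers show. A lower level in the tumour cells is a candidate explanation that goes with the genotype and was not tested on its own.

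Ltf, which encodes lactoferrin, rose from 13.4 ± 7.09 to 988 ± 590 CPM, and Cd53, a leukocyte tetraspanin, from 19.7 ± 13.4 to 218 ± 95.8 CPM. Neutrophils, which the CD45 gate would remove, make Ltf with more abundant S100a8 and S100a9, and these together reached 0.72% of the Ltf level in sgLkb1. The log2 fold change of Ptprc plus 2 SE was 0.69 against 3.47 (SE 0.53) for Cd53. That argues against RNA of leukocytes that express Ptprc as the whole source of the Cd53 rise. The sort took CD45-negative cells, so Ptprc cannot weigh leukocytes low in CD45. Macrophage genes C1qb (1.11 to 6.75 CPM) and C1qc (0.63 to 3.06 CPM) also rose, calls lost without sgNeo replicate 2 (edgeR adjusted p = 0.060 and 0.051). Camera called the macrophage list higher (adjusted p = 0.042, and adjusted p = 0.66 with an estimated correlation). Some macrophage RNA therefore stays open, although the CD45 gate would remove macrophages too. Expression of both genes by sgLkb1 tumour cells is a hypothesis that these libraries do not test further.

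A hypothesis of whole-chromosome copy number differences was tested on chromosome medians. The median farthest from that of all genes was 0.16 on the log2 scale, on chromosome 9 (camera adjusted p = 0.34), within the 0.2 set beforehand, so these data gave no sign of a chromosome-wide shift of that size. A hypothesis that STAT3-induced genes follow the rise of Lif was tested on the list median in each library. The lowest sgLkb1 library was below the highest sgNeo library, a difference of -0.17 log2 CPM, so the libraries overlapped. In sgLkb1 replicates 1 and 2 the list median was 6.34 and 6.26 log2 CPM, below all sgNeo libraries (6.38, 6.42 and 6.39). Lif in those sgLkb1 libraries was 48.7 and 50.7 CPM, above every sgNeo library (at most 33.7 CPM). In them a higher Lif thus came without a higher list median, though the gaps between the medians were small and were not tested. Only sgLkb1 replicate 3 had both the highest list median (6.68 log2 CPM) and the highest Lif (61.5 CPM). It is also the library in which most fibroblast and endothelial markers were highest. Members that passed went both ways (2 higher and 3 lower), so the list median does not settle the hypothesis.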
